A study of Entamoeba histolytica HM-1:IMSS with 12 samples.

How the data were processed

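RNA bound to 4 proteins of Entamoeba histolytica, the amoeba that causes amoebiasis, was measured by crosslinking and immunoprecipitation followed by sequencing (CLIP-seq). In this assay ultraviolet light joins RNA to the proteins that touch it, an antibody pulls down 1 protein, and the RNA that comes with it is sequenced. Per the labels, trophozoites of the strain HM1:IMSS were used, and 12 libraries of 51-base single reads were made, 3 for each antibody. The antibodies were against ARPv2, an orphan actin-related protein, against Nop58 and Fibrillarin, which are core proteins of the box C/D small nucleolar ribonucleoprotein and served as positive controls, and against ABP-120, an actin-binding protein that served as the negative control. The titles of the control libraries name another protein, ABP34, and their group was taken from the label that states the antibody. The columns of the tables are headed EhRPV2 and EhAPB-120 for ARPv2 and ABP-120. They were read as misspelt forms of these names, which no source used here states, and every ARPv2 and control value depends on that reading.

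Per the submitters' processing notes, the tools CASAVA 1.8.2, cutadapt and TopHat2 2.0.6 were used. The layout of the table is that of a Cuffdiff isoform tracking file, per the file headers. The genome build, the annotation, the Cuffdiff version and its settings are not given in the sources used here. The deposited FPKM table gives the authors' fragments per kilobase, scaled for sequencing depth, for 8389 features, with a lower and an upper bound for each value and the length of the feature. It holds 1 value per antibody, so the authors had combined the 3 libraries of each antibody in a way that is not given in the sources used here. A deposited table of log10 values gives log10(FPKM + 1) of the same 4 columns, and the 2 tables differed by at most 0.00169 on that scale because the largest FPKM are rounded in the first. The log10 table was therefore used for computing and the FPKM table for printing.

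The design fixed before the data were examined foresaw limma on the 12 libraries, and for files with 1 value per group it foresaw values side by side with no test. The latter applied. No p-value, standard deviation or n is attached to any value, and no difference between antibodies has a replicate check. Each of the 3 antibodies was compared with ABP-120, the 3 were compared with each other, and their equal-weight mean was compared with ABP-120. A difference is log2(FPKM + 1) of the first antibody minus that of the second. Counts are of features above 0 under both antibodies with a mean FPKM of at least 1 over the 4 columns, and a feature is called higher or lower at a difference of 2-fold or more. On this scale the change of features with low FPKM is understated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

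Features carry coordinates on scaffolds and no gene names. A RefSeq gene table of the assembly JCVI-ESG2-1.0 was used for locus tags and biotypes only. Features were matched to it by their exact start and end: 8030 of the 8389 had the same start and end as a gene, 8028 of them uniquely, and after shifts of 1 to 100 nt no more than 2 matched. Coordinates printed are those of the authors' table, counted from 1. Features without a match were divided by length into short ones of up to 250 nt and longer ones, and they remain unnamed, because nothing used here says which RNA they are. Of 22 gene lists fixed before the data were examined, 1, the tRNA list, could be filled from biotypes. The other 21 need product names, which were not used here.

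The depth behind each value was recovered from the values, a step added after the data were seen. FPKM multiplied by an effective length gave whole multiples of 1 step per column, within a tolerance of 0.02, for 94.6% of the values below 10 steps (542 of 573). The effective length assumes fragments with a mean of 200 nt, an SD of 80 nt and none shorter than 48 nt, and the last number was chosen because it gave the most whole multiples. With the full length in its place 13.0% were whole. Neither the authors' fragment settings nor their read counts were seen, so this reading is inferred. The multiple is called a read equivalent below: 1 read equivalent is the smallest amount that a column resolves. The effective length of a 50-nt feature is 0.00515 nt, against 755.7 nt for one of 960 nt, so a read on a short feature adds far more FPKM than a read on a long one. Intervals are exact Clopper-Pearson intervals at a confidence level of 95%, computed on rounded read equivalents. They cover counting error only, treat amplified reads as independent molecules, and are too narrow where 1 read of a shallow library counts as several equivalents.

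The authors' own bounds were checked against counting error for features under 100 nt and of 500 nt or more, not for lengths between. They did not serve as errors under 100 nt. Among features above 0 under 100 nt the upper bounds were narrower than counting error for 16 of 16 features of ARPv2, 21 of 22 of Nop58, 21 of 21 of Fibrillarin and 20 of 20 of ABP-120, whereas at 500 nt or more this held for 0 of 80, 0 of 239, 0 of 104 and 0 of 99.

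The rule for named features was written before the data were examined. For 1 value per group it takes the 8 largest differences per direction against ABP-120, among features with a mean FPKM of at least 10, and 3 per direction for comparisons among the other antibodies. It adds the 5 features of highest mean FPKM and the tRNA list. Nearly all features it took from the comparisons were at 0 in 1 of the 2 columns, where no fold is given and the feature is said to be listed at 0. The report therefore also names features from the 29 with at least 10 read equivalents under all 4 antibodies and a few others, all chosen after their values were seen.

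The steps were tested on simulated data for ARPv2 against ABP-120, with reads drawn for the real features at 5 times the depth of the ABP-120 column and known 4-fold changes. Values were built from reads with the effective lengths used to recover them, so the fragment settings were not tested. Both columns were drawn at equal depth from the ABP-120 profile with counting error alone. Their known unequal steps were divided out, and no pseudocount was added. Errors from scaling, unequal steps or replicate spread were therefore not tested. The percentages are not error rates of the real comparison. With 10 or more reads in both columns (54 features), 90% of 4-fold higher and 85.7% of 4-fold lower features passed 2-fold, and 0% of unchanged ones did. With any reads (355 features), 79.5% and 84.2% passed, and so did 35.9% of unchanged ones.

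The settings changed, as fixed before the data were examined, were pseudocounts of 0.1 and 5 in place of 1, no filter on the mean and a mean of at least 10, median-of-ratios scaling, quantile normalization, protein-coding features alone, the other deposited table, other limits for counting a feature, Spearman correlation, and shares without the 10 most abundant features. Quantile normalization also limited the features to the 46 above 0 in all columns, and the protein-coding features were also rescaled to a common sum, so these changed the set and the scale together. Added after seeing the data were at least 10 read equivalents under both antibodies, features of at least 60 nt, shares of read equivalents, and equal sums of read equivalents. Median-of-ratios scaling added 0.75 to every log2 difference of ARPv2 from ABP-120, -0.04 to those of Nop58 and -0.36 to those of Fibrillarin. Equal sums added 0.50, 0.05 and -0.12. A direction described as kept under every scaling held as deposited and under these and quantile normalization.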

Results

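CLIP-seq was used to ask which RNAs of Entamoeba histolytica trophozoites are bound by ARPv2, an orphan actin-related protein, in comparison with the nucleolar proteins Nop58 and Fibrillarin and with the negative control ABP-120. The 12 libraries form 4 groups of 3, and the values analysed are the authors' single FPKM per antibody, without replicate error. Of 8389 features, 527 were above 0 under at least 1 antibody and 46 under all 4. ARPv2 had 126 features above 0, Nop58 307, Fibrillarin 160 and ABP-120 156. The depth recovered from the values came to 64928 read equivalents for ARPv2, 274809 for Nop58, 78335 for Fibrillarin and 72557 for ABP-120. A share of 0 therefore allows up to 0.00462% for ARPv2, 0.00109% for Nop58, 0.00383% for Fibrillarin and 0.00413% for ABP-120, at 3 counts of the total and for counting error only.

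Almost all signal lay on features that matched no gene of the RefSeq table. Short unmatched features, of up to 250 nt, held 99.1% of the summed FPKM under ARPv2, 99.3% under Nop58, 99.4% under Fibrillarin and 99.2% under ABP-120. In read equivalents the division was different. The short features held 28.6% under ARPv2 (28.3 to 29.0%), 47.7% under Nop58 (47.5 to 47.9%), 47.7% under Fibrillarin (47.4 to 48.1%) and 20.5% under ABP-120 (20.2 to 20.8%), and unmatched features over 250 nt held 71.2%, 52.1%, 52.0% and 79.3%. Protein-coding features held between 0.190% under Fibrillarin and 0.233% under ABP-120. Altogether 43 short unmatched features were above 0 under at least 1 antibody and 35 under all 4. None of the 43 overlapped another feature, and for the 41 with another feature on their scaffold the median gap to the nearest was 115 nt, with a range of 50 to 543 nt.

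A pair of features set most of this division. A 115-nt feature on scaffold DS571922 (293 to 407) held 25.7% of the read equivalents under ARPv2, 44.5% under Nop58, 44.6% under Fibrillarin and 18.1% under ABP-120. A 1945-nt feature on scaffold DS571673 (1350 to 3294) held 42.0%, 26.6%, 26.9% and 56.8%. For both features ARPv2 lay between ABP-120 and the nucleolar proteins, and the counting intervals of Nop58 (44.3 to 44.6% and 26.5 to 26.8%) overlapped those of Fibrillarin (44.2 to 44.9% and 26.6 to 27.2%). Without the 115-nt feature the short features held 2.91% under ARPv2 (2.78 to 3.04%), 3.25% under Nop58 (3.19 to 3.32%), 3.15% under Fibrillarin (3.03 to 3.28%) and 2.43% under ABP-120 (2.32 to 2.54%). With both leading features left out of the total, these shares were 9.02%, 11.3%, 11.1% and 9.68%. The value of ARPv2 was then below that of ABP-120, but no counting interval was computed for these shares, so this order was not settled.

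**Figure D1:**
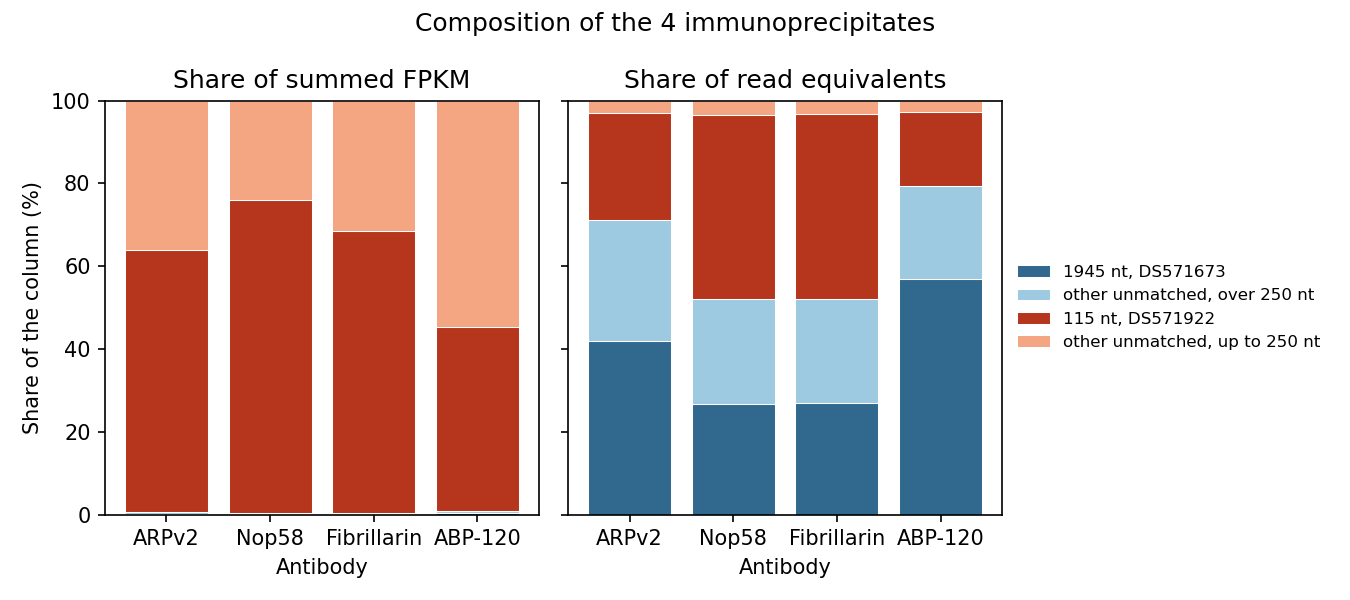
Share of each antibody's column (%), by summed FPKM on the left and by read equivalents on the right, in 4 sets of unmatched features. The 115-nt feature on DS571922 holds 44.5% of the read equivalents under Nop58 and 18.1% under ABP-120; protein-coding and tRNA features are too small to be drawn.

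The comparison of ARPv2 with ABP-120 asks which RNAs the protein of interest recovers above the negative control. Among the 29 features with at least 10 read equivalents under all antibodies, 3 were at least 2-fold higher under ARPv2, each of them short and unmatched, and their direction was kept under every scaling. A 127-nt feature on DS571157 (24136 to 24262), 113 nt from EHI_196950, was higher by 2.46 on the log2 scale (1.52 to 3.51), at 173916 against 31708 FPKM. A 141-nt feature on DS571205 (43056 to 43196), 50 nt from EHI_107180, was higher by 1.65 (1.13 to 2.19), and a 65-nt feature on DS571331 (10242 to 10306) by 1.08 (0.57 to 1.61). Among features with fewer reads in the control, a 119-nt feature on DS571148 (172057 to 172175) reached 77.8 read equivalents under ARPv2 against 4.99, a log2 difference of 3.62 (2.34 to 5.28), and a 104-nt feature on DS571306 (8769 to 8872) 44.4 against 2.00, a difference of 4.13 (2.18 to 7.21).

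More features were lower than higher under ARPv2 in the deposited scale. Among the same 29 features the farthest below was a 133-nt feature on DS571293 (24255 to 24387), at 41499 against 306902 FPKM, a log2 difference of -2.89 (-3.61 to -2.22). Of those among the 29 whose direction was kept under every scaling, it was followed by a 66-nt feature on DS571301 (21232 to 21297) at -1.57, a 349-nt feature on DS571615 (8279 to 8627) at -1.50 and a 537-nt feature on DS571673 (484 to 1020) at -1.22. The 115-nt feature on DS571922 was level in FPKM, with a difference of 0.00 (-0.03 to 0.04), and higher by 0.75 with median-of-ratios scaling. In all, 6 of 50 features were higher and 22 lower, with a median of -0.87, which moved to -0.12 with median-of-ratios scaling, 0 with quantile normalization of the 46 features above 0 in all columns (-0.93 for these as deposited), -0.37 with equal sums and -0.26 with at least 10 read equivalents in both columns. The split was 13 against 11 with median-of-ratios scaling, 8 against 9 with quantile normalization and 10 against 15 with equal sums of read equivalents. Among the 29 features with at least 10 read equivalents it was 3 against 10 as deposited, 8 against 2 with median-of-ratios scaling and 5 against 5 with equal sums, so the direction of the whole set was not fixed by these values. The authors' bounds lay above those of the control for 6 features, below for 19, and overlapped for 25.

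Nop58 against ABP-120 shows what a box C/D core protein recovers. The 115-nt feature on DS571922 was higher by 1.24 (1.22 to 1.27), at 135000000 against 57000000 FPKM, and the 1945-nt feature on DS571673 was lower, with a difference of -1.15 (-1.16 to -1.13). The 141-nt feature on DS571205 was higher by 1.78 (1.30 to 2.28), and a 243-nt feature on DS571673 (1 to 243) by 1.66 (1.29 to 2.05). A 123-nt feature on DS571164 (102495 to 102617) reached 99931 against 9851 FPKM, a difference of 3.34 (1.75 to 5.63), and a 72-nt feature on DS571145 (384474 to 384545) was higher by 3.04 (1.45 to 5.34), although both control values rested on 3 read equivalents. Lower under Nop58 were a 74-nt feature on DS571296 (17307 to 17380), at -1.36 (-2.25 to -0.45), and the 349-nt feature on DS571615, at -0.96 (-1.04 to -0.89). Except for the 115-nt feature, which quantile normalization sets to 0 because it is the highest of every column, these directions were kept under every scaling. Of 68 features 13 were higher and 20 lower, and on the 46 features above 0 in all columns 10 against 8, or 6 against 6 after quantile normalization. Of the 20, 6 had equal rounded read equivalents in both columns and differed only in the FPKM that 1 read equivalent stands for. With at least 10 read equivalents in both columns 6 of 40 were higher and 7 lower. The authors' bounds lay above for 10 features, below for 11, and overlapped for 47. The 141-nt feature was among those above. The 115-nt, 1945-nt, 243-nt and 349-nt features were among those that overlapped. The authors' bounds thus did not separate these from the control, although their counting intervals were narrower.

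Fibrillarin, the methyltransferase of the same particle, gave a similar set of leading features. Against ABP-120 the 115-nt feature was higher by 1.42 (1.39 to 1.45), the 141-nt feature on DS571205 by 2.05 (1.53 to 2.59) and the 243-nt feature on DS571673 by 1.50 (1.07 to 1.94). The 1945-nt feature was lower, with a difference of -0.96 (-0.99 to -0.94), and so was an 84-nt feature on DS571157 (37867 to 37950), at -1.26 (-2.14 to -0.38). A 482-nt feature on DS572121 (891 to 1372) was at 3826 against 19251 FPKM, a difference of -2.33 (-2.71 to -1.96), while under Nop58 it was at 22127 FPKM. A 1475-nt feature on DS572125 (297 to 1771) was higher by 1.25 (1.16 to 1.34), against 0.09 under Nop58, where quantile normalization turned the sign. Apart from the 115-nt feature, set to 0 by quantile normalization, the Fibrillarin directions named here were kept under every scaling. Of 64 features 13 were higher and 9 lower, but 9 against 15 with median-of-ratios scaling. On the 46 features they were 10 against 7, or 6 against 7 after quantile normalization. The authors' bounds lay above for 16 features, below for 6, and overlapped for 42. The 141-nt feature was among those above and the 84-nt feature among those below. The 115-nt, 243-nt, 1945-nt, 482-nt and 1475-nt features were among those that overlapped, although their counting intervals were narrower.

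**Figure D2:**
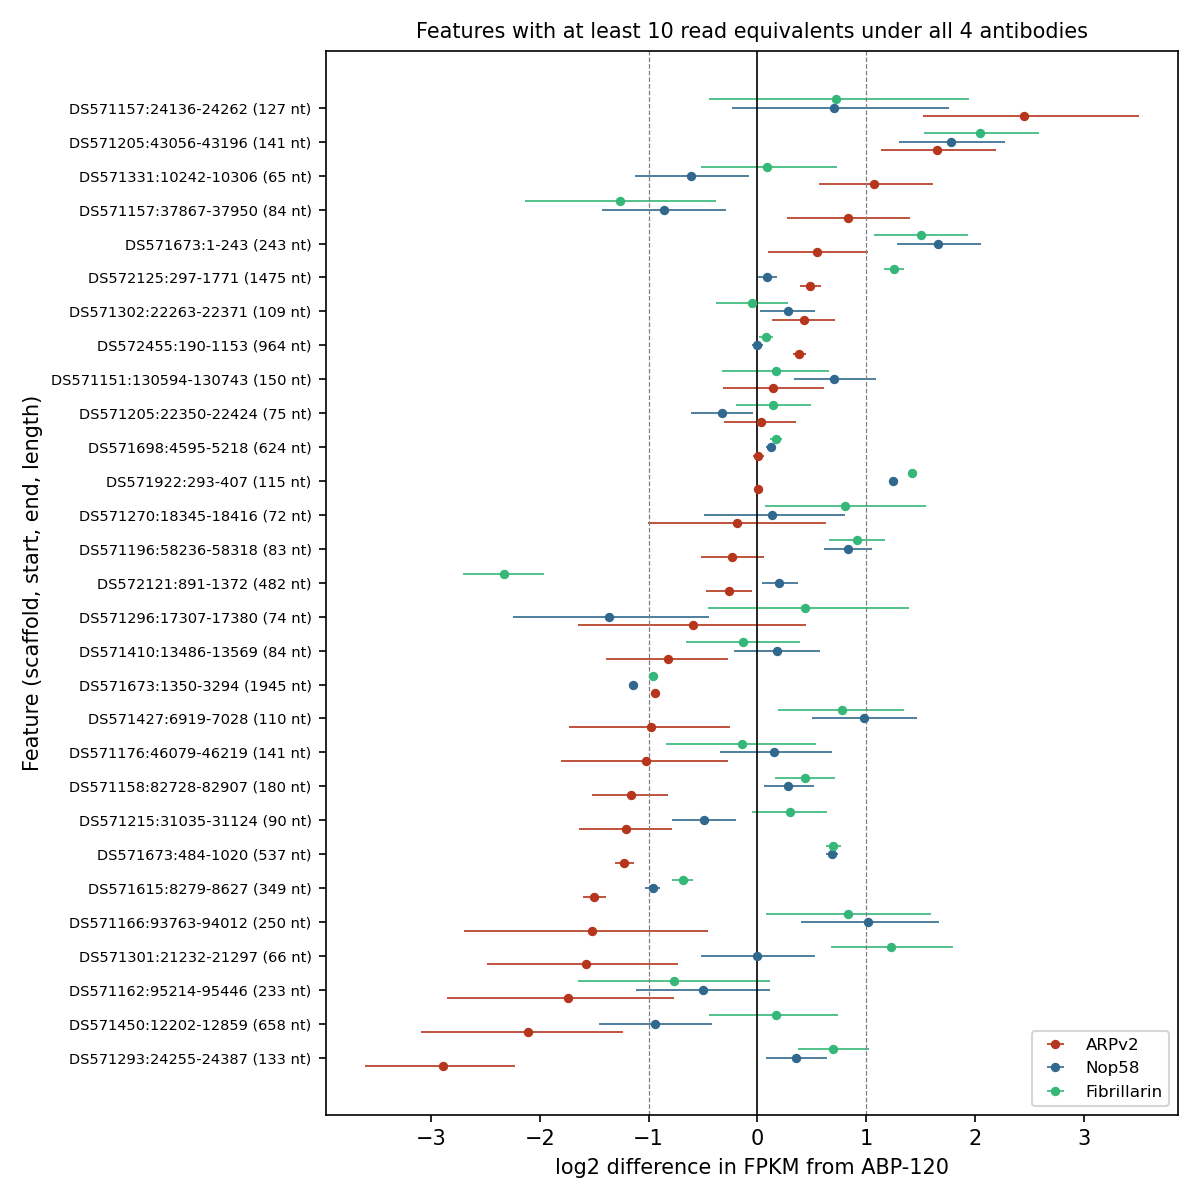
log2 difference in FPKM from ABP-120 (horizontal axis) for the 29 features with at least 10 read equivalents under all 4 antibodies; points are the authors' single values as deposited and bars are intervals of 95% for counting error only. The 141-nt feature on DS571205 lies above 1 for all 3 antibodies, and the 537-nt feature on DS571673 lies at -1.22 for ARPv2 and at 0.68 and 0.70 for Nop58 and Fibrillarin.

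Among the 46 features above 0 in all columns, 3 were at least 2-fold higher under all 3 antibodies: the 141-nt feature on DS571205, the 119-nt feature on DS571148 and the 104-nt feature on DS571306. For the 119-nt feature the differences were 3.62 under ARPv2, 1.47 (0.15 to 3.14) under Nop58 and 2.39 (0.98 to 4.12) under Fibrillarin, and for the 104-nt feature 4.13, 1.52 (-0.54 to 4.62) and 1.18 (-1.28 to 4.72). Under quantile normalization the 119-nt feature fell to 0.44 for Nop58 and the 104-nt feature to 0.51 for Fibrillarin, where median-of-ratios scaling gave 0.82. The 141-nt feature alone stayed 2-fold higher under all 3 antibodies with every scaling. The 4 features lower under all 3 were a 140-nt feature on DS571156 (30591 to 30730), at -2.83, -1.26 and -1.99, a 54-nt feature on DS571468 (9630 to 9683), at -1.85, -1.31 and -1.38, a 50-nt feature on DS571416 (15678 to 15727), at -2.80, -2.85 and -1.64, and the protein-coding EHI_130700. The 50-nt feature rested on at most 11 read equivalents in any column and EHI_130700 on at most 5.00, and quantile normalization set the Fibrillarin difference of the first and each difference of the second to 0. The 54-nt feature had 5.99 read equivalents under ARPv2 and 6.51 under Fibrillarin, with a Fibrillarin interval of -2.79 to 0.07. Quantile normalization left it at -0.87 for ARPv2 and -0.33 for Nop58. The 140-nt feature stayed 2-fold lower under all 3 antibodies with every scaling, but had 4.99 read equivalents under ARPv2 and 6.99 under Fibrillarin. Of the 3 higher features, the 141-nt one alone had at least 10 read equivalents in every column.

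ARPv2 and Nop58 shared 3 higher features, against 1.30 for independent lists, ARPv2 and Fibrillarin 4 against 1.30, and Nop58 and Fibrillarin 7 against 2.17. Simulated unchanged columns against the same control shared 1.83, 1.82 and 1.79 higher features, with a noise SD of 0.59 on the log2 scale in every column. This SD was derived from the differences between Nop58 and Fibrillarin over the 46 features above 0 in all columns. Any real difference between that pair is thus counted as noise, and the same SD was assumed for the other columns. The replicate spread is unknown, so the simulated numbers do not decide what is shared. The numbers of shared lower features were 6, 5 and 4 in the same order, against 3.65, 3.20 and 1.22 for independent lists. Among the 29 features with at least 10 read equivalents in every column, the pairs shared 1, 1 and 3 higher features, against 0.41, 0.52 and 0.69, and 0, 0 and 0 lower ones, against 0.69, 0.69 and 0.14. All of these comparisons use the same control column, which could not be split, and part of each excess may come from it. Across the 46 features the differences from the control had a Pearson r of 0.41 for ARPv2 and Nop58, 0.50 for ARPv2 and Fibrillarin and 0.74 for Nop58 and Fibrillarin. Simulated unchanged columns against the same control gave 0.50, a value that equal noise in every column fixes in advance, so it decides nothing about sharing. The covariances were 0.82, 0.90 and 0.98 in the same order, against 0.34, 0.34 and 0.35 simulated. The simulated covariances rest on the same noise SD, so this excess does not decide it either. Features are not independent replicates. For the mean of the 3 antibodies 7 of 46 features were higher and 11 lower, and 8 against 8 with median-of-ratios scaling or equal sums.

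Nop58 and Fibrillarin were the most alike pair. The Pearson correlation of log2(FPKM + 1) across the 46 features was 0.984 for them, 0.941 for ARPv2 and Nop58, 0.952 for ARPv2 and Fibrillarin, and 0.937, 0.965 and 0.972 for ARPv2, Nop58 and Fibrillarin with ABP-120. The effective lengths, which are the same in every column, enter these values. On log2 read equivalents they were 0.969, 0.899, 0.917, 0.890, 0.935 and 0.946 in the same order. ARPv2 correlated less with either nucleolar protein than these did with the control. An 84-nt feature on DS571157 (37867 to 37950) differed from ABP-120 by 0.83 (0.27 to 1.40) under ARPv2, by -0.86 (-1.43 to -0.29) under Nop58 and by -1.26 under Fibrillarin, and the 537-nt feature on DS571673 by -1.22, 0.68 and 0.70. These directions were kept under every scaling. A 108-nt feature on DS571145 (496742 to 496849) was listed at 0 under ARPv2, with 128 read equivalents under Nop58, 29.1 under Fibrillarin and 26.5 under ABP-120. A 53-nt feature on DS571163 (50681 to 50733) and a 79-nt feature on DS571530 (11714 to 11792) were also listed at 0 under ARPv2, with 29.5 and 35.5 read equivalents under Nop58. Against Nop58, ARPv2 had 18 of 66 features higher and 23 lower, but 26 against 10 with median-of-ratios scaling, 22 against 14 with equal sums, 8 against 23 at a mean of at least 10 FPKM and 5 against 12 with at least 10 read equivalents in both columns. Of the 18, 9 had equal rounded read equivalents in both columns. Against Fibrillarin it had 7 of 54 higher and 22 lower, but 13 against 9 with median-of-ratios scaling, 8 against 11 with quantile normalization, 9 against 13 with equal sums and 4 against 11 with at least 10 read equivalents. Nop58 had 9 of 78 features higher than Fibrillarin and 20 lower, 10 against 14 with median-of-ratios scaling, 4 against 2 with quantile normalization and 2 against 5 with at least 10 read equivalents, and 5 of the 20 lower ones had equal rounded read equivalents.

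Little signal lay on features matched to tRNA genes. Any tRNA on the unmatched features, which could not be identified, is not counted here. Of 77 tRNA genes of RefSeq, 7 were above 0 under any antibody, and none under all 4. EHI_103040 on DS572064 (1802 to 1872) had 31.5 read equivalents under Nop58, 9.03 under Fibrillarin and 4 under ARPv2, and was listed at 0 under ABP-120. The other 6 rested on 1 read equivalent in any column: EHI_037650 and EHI_072360 under ABP-120, EHI_083000 and EHI_161430 under Nop58, EHI_157570 under Fibrillarin, and EHI_106910 under both Nop58 and Fibrillarin. For EHI_103040 the counting interval of the log2 difference from ABP-120 began at 1.01 for Nop58, at 0.99 for Fibrillarin and at -0.94 for ARPv2, so a difference between ARPv2 and the control was not detectable at this depth. If libraries of unequal depth were averaged, as discussed below, its Nop58 and Fibrillarin values may rest on fewer reads. The limits for these antibodies would then be too high.

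The other features taken by the naming rule included many that a single antibody recovered. This was common among all features: of the 527 above 0, 419 were above 0 under 1 antibody only, 402 of them protein-coding. Recovery under a single antibody at few read equivalents therefore does not show binding particular to that protein. A 479-nt feature on DS572121 (1 to 479) had 265.7 read equivalents under ARPv2, 912.3 under Nop58 and 3.52 under Fibrillarin and was listed at 0 under ABP-120. The protein-coding EHI_160980 on DS571228 (37786 to 38745) had 40.4 read equivalents under ARPv2, 2.00 under Nop58 and was listed at 0 under the other antibodies. EHI_171300 and EHI_009500 were listed above 0 under ARPv2 alone, at 1 read equivalent. EHI_020990, at 14.5 read equivalents, and EHI_023220, at 3.00, were recovered under Nop58 alone. EHI_154700, at 2.52, and EHI_068480, at 1, were recovered under Fibrillarin alone, which shared EHI_023840 and EHI_069450 with Nop58. EHI_096570 and EHI_151290, at 6.85 each, EHI_023230, at 2.00, and EHI_170340 and EHI_149000, at 1, were recovered under ABP-120 alone, and EHI_176140 under ABP-120 and Nop58. Another 6 features taken by the rule were unmatched, of 84 to 441 nt, and had at most 4.99 read equivalents in any column. Besides the 115-nt feature, the highest mean FPKM belonged to 4 features of 50 to 83 nt, among them the 50-nt feature on DS571416, whose 31000000 FPKM under ABP-120 rested on 11 read equivalents, and an 83-nt feature on DS571196 (58236 to 58318), with 1350 read equivalents under Nop58.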

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

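No paired analysis was possible because the tables give 1 value per antibody. For the same reason leaving out single libraries, fits of 2 groups, the F test over the 4 antibodies, gene set tests and calls at an unadjusted p were not run. Of 273 values under alternatives, 173 stayed within their limits, 92 moved and 8 reversed. The alternatives added after seeing the data were those on read equivalents and on length. A pseudocount of 0.1, no filter on the mean and the other deposited table left every count of higher and lower features within 1.5 times. Of the 307 Nop58 features 176 rested on 1 read equivalent, and of the 126 ARPv2 features 62. Causes of moves under the alternatives were not tested. With a mean of at least 10 FPKM, ARPv2 had 8 features higher than Nop58, and features of at least 10 FPKM numbered 81 for ARPv2 and 99 for Nop58.

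Median-of-ratios scaling gave 13 higher and 11 lower features for ARPv2 against ABP-120, 15 lower for Fibrillarin against ABP-120, 10 lower for ARPv2 against Nop58, and 13 higher and 9 lower for ARPv2 against Fibrillarin. It reversed the median log2 difference to -0.22 for Fibrillarin against ABP-120, 0.66 for ARPv2 against Nop58 and 0.25 for ARPv2 against Fibrillarin. Quantile normalization, run on the 46 features above 0 in all columns, gave 9 lower for ARPv2 against ABP-120, 6 higher and 6 lower for Nop58 against ABP-120, 6 higher for Fibrillarin against ABP-120, 9 higher and 10 lower for ARPv2 against Nop58, 11 lower for ARPv2 against Fibrillarin, 4 higher and 2 lower for Nop58 against Fibrillarin, and 4 higher and 7 lower for the mean of the 3 antibodies. Part of these moves belongs to the smaller set: as deposited, the same 46 features gave 6 higher and 21 lower for ARPv2 against ABP-120, 10 and 8 for Nop58, 10 and 7 for Fibrillarin, 6 and 21 for ARPv2 against Nop58, 5 and 20 for ARPv2 against Fibrillarin, and 4 and 6 for Nop58 against Fibrillarin. Equal sums of read equivalents gave 10 higher for ARPv2 against ABP-120, 14 lower for ARPv2 against Nop58, with the median reversed to 0.31, and 13 lower for ARPv2 against Fibrillarin.

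Protein-coding features alone, rescaled to a common sum, numbered 2 to 25 per comparison. They gave 3 higher and 0 lower of 5 for ARPv2 against ABP-120, 2 and 10 of 19 for Nop58 against ABP-120, 3 and 3 of 14 for Fibrillarin against ABP-120, 16 and 0 of 18 for ARPv2 against Nop58, 2 and 0 of 6 for ARPv2 against Fibrillarin, 4 and 10 of 25 for Nop58 against Fibrillarin, and 1 and 1 of 2 for the mean of the 3. Their medians were reversed to 1.70 for ARPv2 against ABP-120, 2.02 for ARPv2 against Nop58 and 0.65 for ARPv2 against Fibrillarin. Without rescaling, the same features had medians of 0.58, 1.28 and -0.31, so the first 2 were positive before it. Their counts were then 1 higher and 2 lower, 12 and 1, and 1 and 1. Against ABP-120 they were 2 and 12 for Nop58 and 3 and 3 for Fibrillarin, and 4 and 11 for Nop58 against Fibrillarin. These rows rest on few read equivalents, and 1 read equivalent stands for 3.10 times as much FPKM in ARPv2 as in Nop58. For ARPv2 against Nop58, 9 of the 18 features had equal rounded read equivalents and all 9 counted as higher, so neither the 16 nor the reversed median shows a difference in binding. Requiring 10 or more read equivalents in both columns gave 3 higher and 10 lower for ARPv2 against ABP-120, 6 and 7 for Nop58 against ABP-120 with the median reversed to 0.11, 6 and 2 for Fibrillarin against ABP-120, 5 and 12 for ARPv2 against Nop58, 4 and 11 for ARPv2 against Fibrillarin, 2 and 5 for Nop58 against Fibrillarin, and 3 and 3 for the mean of the 3.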

Other observations

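Features of the same scaffold differed in direction on DS571673, which, like DS572121, was chosen after its values were seen. There the 243-nt feature (1 to 243) differed from ABP-120 by 0.55 under ARPv2, 1.66 under Nop58 and 1.50 under Fibrillarin, the 537-nt feature (484 to 1020) by -1.22, 0.68 and 0.70, and the 1945-nt feature (1350 to 3294) by -0.94, -1.15 and -0.96, with each sign kept under every scaling. On DS572121 the 479-nt feature was listed at 0 under ABP-120 while the 482-nt feature had 368 read equivalents there, and under Fibrillarin they had 3.52 and 72.9. In the deposited scale, features over 500 nt at nearly level FPKM under every antibody included a 624-nt feature on DS571698 (4595 to 5218), at 186387 under ARPv2, 202052 under Nop58, 208342 under Fibrillarin and 185311 under ABP-120, but its ARPv2 difference was 0.76 with median-of-ratios scaling and 0.51 with equal sums.

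Protein-coding RNA was scattered over many genes. Of 455 protein-coding features above 0, 2 were above 0 under all 4 antibodies, 313 had 1 read equivalent under a single antibody, and 12 had at least 10 under any. If libraries of unequal depth were averaged, as discussed below, these 12 may rest on fewer reads than their read equivalents. EHI_182860 had 44.5 read equivalents under Nop58 and 1.00 under ABP-120, EHI_111990 had 42.0 under Nop58 and 5.00 under ARPv2, and EHI_006860 had 24.5 under Nop58 and 2.00 under Fibrillarin. EHI_167710 had 13.7 under ABP-120 alone. Under Nop58 EHI_098570, EHI_148710 and EHI_020990 each had 14.5, and EHI_167130, EHI_011210 and EHI_148270 each had 15.5.

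All tests below were chosen after the results were seen. Features under 100 nt held 33.2% of the summed FPKM under ARPv2, 22.1% under Nop58, 30.1% under Fibrillarin and 52.7% under ABP-120, but 1.26%, 1.23%, 1.40% and 1.11% of the read equivalents. A candidate explanation is an effective length near 0 for features shorter than the assumed fragments: with it 94.6% of low values were whole multiples of 1 step, against 13.0% with the full length. The control's FPKM share owed 24.2% of the column to the 50-nt feature on DS571416 alone, at 11 read equivalents. RNA bound by the nucleolar proteins stays open: it would leave the control with the lowest share of read equivalents. The control was lowest at 1.11%, but its counting interval (1.033 to 1.187%) overlapped that of ARPv2 (1.17 to 1.35%). The intervals of Nop58 (1.189 to 1.271%) and Fibrillarin (1.319 to 1.485%) lay above that of the control, the first only just. All of them cover counting error only and there is no replicate check, so they do not decide the question.

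Nop58 listed 307 features above 0, and the other antibodies 126 to 160. Thinned to the 64928 read equivalents of ARPv2 in 100 draws, the Nop58 column kept 133.03 features on average, with a highest draw of 149, against an average of 146.61 for ABP-120. The draws treat read equivalents as independent reads. With a further step of 14.5 in the Nop58 column, described below, its number of reads is unknown. The column may therefore have been thinned too far. The ranges also overlapped, at 119 to 149 for Nop58 and 138 to 153 for ABP-120. The lower mean thus does not decide whether Nop58 bound a wider set of transcripts. The greater depth of its column may account for the longer list.

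Low values were whole multiples of 1 step for 100% of ARPv2 and of Nop58 features but for 79.0% of Fibrillarin and 94.7% of ABP-120 features. Nop58 had broken multiples further up, and so had ARPv2, among them 40.4 for EHI_160980 and 44.4 for the 104-nt feature on DS571306. A column averaged from libraries of unequal depth would hold a further step, the worth of 1 read in a shallower library, and such a step, taken from the lowest broken value, was tested on the higher ones. It accounted for 30 of 30 values for Fibrillarin (step 2.52; 95th percentile of other steps 21) and 12 of 16 for Nop58 (step 14.5; 95th percentile 8.05), so unequal libraries are a candidate explanation there. For ABP-120 it accounted for 9 of 21 (median of other steps 5, 95th percentile 12), a value between both, which leaves it open. ARPv2 was not tested for a further step, so its higher read equivalents and their counting intervals carry the same doubt. Under the hypothesis of unequal libraries the Nop58 genes at 14.5 read equivalents may each rest on 1 read. Those at 15.5, 24.5, 42.0 and 44.5 may rest on fewer reads than these numbers. EHI_154700, whose 2.52 equals the Fibrillarin step, may rest on 1 read too. EHI_096570 and EHI_151290 lay at the ABP-120 step of 6.85, so they and EHI_167710 at 13.7 are open to the same doubt. So are the tRNA EHI_103040, at 31.5 under Nop58 and 9.03 under Fibrillarin, and the 104-nt feature on DS571306, at 22.5 and 4.51. No biological explanation was tested.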
